A study of Caenorhabditis elegans with 2 samples.

How the data were processed

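SPTF-1 ChIP-seq was measured in 2 biological replicates of mixed-stage embryos. Per the labels, chromatin was sonicated. The sample description names an anti-GFP antibody for the precipitation, whereas the antibody field of the labels names sptf-1. For each of the ce10 and ce11 builds, the authors deposited a list of 30000 regions per replicate, a list of 30000 regions from both replicates together, and a thresholded list. Per the deposited file listings, the regions were called on alignments with a control file, and the thresholded list was the optimal set of an irreproducible discovery rate (IDR) analysis. The aligner, the peak caller, the IDR cutoff and the read depth were not given in the sources used here, and the control's own values were not used here. A deposited region carries the authors' signal value, a −log10 q value and a summit position. Most thresholded peaks, 1725 of 2430 in ce11, share the highest −log10 q in the deposited list, so peaks were ranked by the authors' signal value. Signal values of different lists are not on one scale, and ranks were used between replicates.

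The ce11 lists were the main ones, since the reference genome and annotation used here were of that build. The last region on each of 7 chromosomes ended within the reference length. The ce10 lists, with 2416 thresholded peaks, were used only for counts, replicate overlap and the replicate signal correlation. Each ce10 chromosome's length was taken as the end of its last region. The ce11 thresholded list was identical to the 2430 strongest regions of the pooled list. Regions in a list can overlap, and the 2430 peaks have 2421 distinct intervals. Of the 1714 top regions shared by both replicates, 11 overlapped no region of the pooled list, and 2 of these lay within 20 kb of the middle of sptf-1, so the pooled list has gaps.

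A promoter window ran from 1000 bp upstream to 500 bp downstream of the 5' end of a protein-coding transcript. A gene had a promoter peak if a thresholded summit fell in a window of it, so that 1 summit may count for several genes. Promoter shares, RNA gene shares and replicate overlaps were tested by 10000 circular shifts along each chromosome, two-sided as 2 times the smaller tail, and one-sided for replicate overlap. Gene lists and motifs were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment with a threshold of 0.05. X against autosomes and centres against arms were tested in the same way, but without adjustment. Neighbouring genes share peaks, which can make Fisher's p too small, so gene lists also had a circular-shift p, from the log2 odds ratio with 0.5 added to each count. Shifted peaks marked a mean of 792 genes, against 1650, so with a count of 0 no shift reached the observed value, and the 2 lists with no member were left out of this test after the values were seen. For these 2 lists, the share of the genes with a peak was compared with the shifts instead. Intervals are exact (Clopper-Pearson for shares) at 95%. Odds ratios are conditional estimates, except for 6-mers, where 0.5 was added to each count. GC-matched windows, 2 per summit, came from promoter windows without a peak in bins of 5 percentage points, and 4 summits without a match were left out. Unique tRNA sequences were compared with 1000 shifts.

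Most of the genes named were fixed by rule before the data were examined. These were the Sp and KLF family and unc-119, the genes nearest the 25 strongest promoter peaks found in both replicates, up to 3 members with a peak per gene list (in the text, for lists past the threshold and several tissue lists), and the 10 6-mers of highest odds ratio. The snoRNA, snRNA and miRNA genes named, with the host gene frm-7, fall outside the rule and were chosen after their values were seen. The snoRNA, snRNA, miRNA, lincRNA, piRNA and pseudogene classes, the shares outside promoter windows, the comparison of stronger with weaker peaks at them, the motifs by class and the 9-mer were chosen after the values were seen. Alternatives covered the promoter window, gene assignment, overlap rule, N, build, window width, control windows, a stricter peak set and each replicate alone.

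The tests were run on simulated data first. Random summits gave a promoter call in 4 of 100 simulations, and 20 summits planted at tRNA genes were called in 100 of 100. A list with 30% of its genes bound, where other genes had 8%, was called in 86 of 100 simulations, and 7 of 2722 unplanted lists were called. With no word planted 0 6-mers were called, and a GC box planted in 200 windows took place 1 of 10 called words. In the gene list and 6-mer simulations each gene was bound independently, and all windows came from random places. Neighbouring genes that share peaks and the higher GC content of summit windows were not simulated. The low rates of false calls therefore need not hold for the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.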

Results

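The series profiled where SPTF-1, a zinc-finger transcription factor of the Sp family, was found on the genome of Caenorhabditis elegans embryos. Chromatin immunoprecipitation was carried out on whole organisms of strain OP707, which carries a transgene coding for SPTF-1 with a C-terminal GFP and FLAG tag. The sample description names an anti-GFP antibody and the antibody field names sptf-1, and which was used was not settled here. The embryos were of mixed stages and both sexes, 2.5 hours after egg bleaching. There was 1 group with 2 biological replicates, so no comparison between conditions was made. Read depth behind the lists is unknown, and intervals below cover the number of peaks, genes or windows only.

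The first question was how many sites the replicates shared. The authors' thresholded list held 2430 peaks on the ce11 genome build, of which 2419 were nuclear and 11 mitochondrial. Among the 2430 strongest regions of replicate 1, 1714 (70.5%, exact 95% interval 68.7 to 72.3%) shared at least 1 base with the 2430 strongest regions of replicate 2. Circular shifts of replicate 2 along its chromosomes gave a mean of 55.8 shared regions and at most 91 (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). Of the thresholded peaks, 1699 (69.9%, interval 68.1 to 71.7%) overlapped a top region in both replicates, 374 in replicate 1 only, 302 in replicate 2 only and 55 in neither. Across 2414 peaks with a region in each replicate, Pearson's r of the log2 signal value was 0.87 and Spearman's rho was 0.719. These are correlations across peaks, which are not independent replicates.

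**Figure D1:**
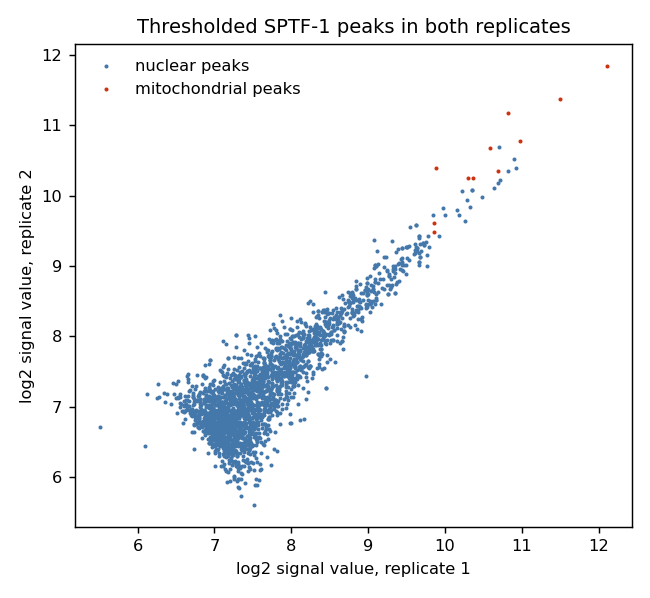
Log2 signal value of the best overlapping region in replicate 1 (x axis) and replicate 2 (y axis), 1 point per thresholded peak, with mitochondrial peaks in red. The 2414 points had a Pearson's r of 0.87 and a Spearman's rho of 0.719.

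The second question was which genes lay beside the sites. The strongest nuclear peak away from small RNA genes lay 529 bp upstream of K12H4.5, at III:8043771-8044166, with a signal value of 3328, as the authors' caller gave it, and ranks 9 and 5 in replicates 1 and 2. The promoter of ftt-2, an adaptor protein gene on X, carried a pair of summits at 11605921 and 11606126 with signal values of 2389 and 1323. The ribosomal protein gene rpl-3 had a peak at III:3867399-3867766, with a signal value of 2269. Its summit lay 268 bp upstream of the transcription start site (TSS), taken throughout as the annotated 5' end of a transcript. Peaks at atx-2, which codes for an RNA-binding protein, and at the protease gene tasp-1 had summits 63 and 69 bp upstream of the TSS, with signal values of 1999 and 1897. The glutamyl-tRNA synthetase gene ears-2 had its summit 28 bp upstream, at IV:390496, with a signal value of 1858. Further strong promoter peaks lay at rpl-15 (1494), T13C5.6 (1494), the isocitrate dehydrogenase subunit gene idhg-1 (1479), the sorting nexin gene snx-13 (1369), nmad-1 (1355), tos-1 (1295) and M01F1.9 (1292).

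The 25 strongest promoter peaks found in both replicates belonged to 24 genes, and all ranked 90 or better in replicate 1 and 67 or better in replicate 2. Both ftt-2 summits lay in the same interval and took the ranks of the same regions, 16 and 17 in replicates 1 and 2. Of the 25 peaks, 11 had a summit within 200 bp of a tRNA, snoRNA, snRNA or miRNA gene. They were assigned to twk-5, sre-23, T02E1.2, Y43F8C.7, cfim-2, F55A11.6, gcy-33, C28G1.2, wrt-3, col-85 and egg-5. The peak at twk-5, a potassium channel gene, lay in an intron that holds the snoRNA gene B0334.12, and the peak at the chemoreceptor gene sre-23 lay beside the snoRNA gene ZK265.10.

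Of the 2419 nuclear summits, 1333 (55.1%, exact 95% interval 53.1 to 57.1%) lay in a promoter window, from 1000 bp upstream to 500 bp downstream of a protein-coding TSS. The mean over circular shifts was 31.1% (SD 0.977), a 1.77-fold difference (two-sided permutation p = 0.0002, the smallest that the shifts can give). The top regions of replicate 1 alone gave 53.2% and those of replicate 2 alone 56.1%. Among the 1086 summits outside promoter windows, 467 lay in introns (43.0%, against 36.4% in the shifts), 417 between genes (38.4% against 31.4%) and 149 in non-coding genes or pseudogenes (13.7% against 4.43%). Coding exons held 36 (3.31% against 24.1%) and 3' UTRs 14 (1.29% against 3.39%). These 5 classes each had a permutation adjusted p of 0.00024 over 6 classes, at the smallest raw p that the shifts can give. As a share of all 2419 nuclear summits, these same intron and between-gene counts were below the shift mean (0.77-fold and 0.797-fold, two-sided permutation p = 0.0002 each). Both counts leave out summits in promoter windows, whose share was above the shifts. They therefore do not measure introns or places between genes over all summits. The higher shares were measured only among the summits outside promoter windows. In all, 1650 of 19973 protein-coding genes (8.26%) had a promoter peak.

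Gene groups were compared next, over 29 lists fixed before the data were examined. Genes for the cytosolic ribosome stood highest, with promoter peaks at 45 of 80 (56.3%, interval 44.7 to 67.3%) and an odds ratio of 14.6 against all other genes (95% interval 9.18 to 23.5, Fisher's exact test, adjusted p = 5.03e-27, circular-shift adjusted p = 0.0027). Its strongest members were rpl-3, rpl-15 and rpl-35, the last with a signal value of 1268. The top regions of replicate 1 marked 41 of these genes and those of replicate 2 marked 43. With each summit given to its nearest TSS only, the odds ratio fell to 8.26 (interval 5.00 to 13.4).

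Other groups of broadly expressed genes also had more promoter peaks than the remaining genes. Mitochondrial respiratory chain genes had peaks at 15 of 46 (odds ratio 5.41, interval 2.71 to 10.4, Fisher's exact test, adjusted p = 1.84e-05), led by cox-5B (905), cox-5A (717) and the cytochrome gene cyc-1 (640). Splicing factors had 11 of 36 (odds ratio 4.91, interval 2.18 to 10.4, Fisher's exact test, adjusted p = 0.000423), among them snr-1, whose peak (1369) was also that of snx-13, and the SR protein genes rsp-1 and rsp-2, which shared a peak of signal value 693. The top regions of replicate 1 marked 8 of them (odds ratio 3.31) and those of replicate 2 marked 16 (8.69). Cell cycle and DNA replication genes had 14 of 49 (odds ratio 4.47, interval 2.22 to 8.54, Fisher's exact test, adjusted p = 0.000134), with cdc-48.1 (1167), the retinoblastoma homologue lin-35 (701) and the CDK inhibitor gene cki-1 (465). Proteasome genes had 9 of 33 (odds ratio 4.18), including rpn-7 (571), rpn-3 (485) and rpn-11 (319). Translation factors and tRNA synthetases had 19 of 70 (odds ratio 4.17), with eif-3.C (1151) and iff-2 (771) after ears-2. Chaperones had 16 of 59 (odds ratio 4.16), with hsp-60 (1082), dnj-29 (1050) and dnj-13 (873), and an odds ratio of 6.46 with replicate 1's top regions alone. Mitochondrial ribosomal proteins had 15 of 70 (odds ratio 3.05), with mrps-28 (2017), mrpl-23 (695) and mrpl-12 (535). The summits of mrps-28 and mrpl-23 lay within 200 bp of snoRNA genes, and the first was also the peak of Y43F8C.7. Histone genes had 17 of 81 (odds ratio 2.97), with his-67 and his-68 at a shared peak (1150) and his-37 (449). For the proteasome, translation, chaperone, mitochondrial ribosome and histone lists, in that order, the adjusted p of Fisher's exact test was 0.00288, 1.84e-05, 9.10e-05, 0.00145 and 0.000906, and the circular-shift adjusted p was 0.0426, 0.0126, 0.0126, 0.0364 and 0.0437. With replicate 1's top regions alone the mitochondrial ribosome and proteasome lists lost their calls (odds ratios 1.71 and 2.07, Fisher's exact test, adjusted p = 0.225 and 0.294), and the proteasome list also lost its call with the upper part of the peaks by signal (odds ratio 1.99, adjusted p = 0.406). With each summit given to its nearest TSS only, the splicing, histone, chaperone and cell cycle lists lost theirs (odds ratios 2.43, 2.13, 2.03 and 2.52, Fisher's exact test, adjusted p = 0.147, 0.0875, 0.173 and 0.0875).

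Body wall muscle genes had peaks at 9 of 47 (odds ratio 2.64, interval 1.12 to 5.56, Fisher's exact test, adjusted p = 0.0264), led by unc-112 (458), lim-8 (452) and unc-60 (445), but the circular-shift adjusted p was 0.618. It lost its Fisher call with windows of 500 bp and of 2000 bp upstream, with the stronger peaks, with replicate 2's top regions and without summits near tRNA genes (odds ratios 2.13, 2.22, 1.85, 2.22 and 2.40). Chemoreceptor genes had peaks at 10 of 1309 (0.764%, odds ratio 0.0799, interval 0.0382 to 0.148, Fisher adjusted p = 2.93e-35, circular-shift adjusted p = 0.0027). Their 3 strongest were sre-23, sre-1 (1133) and sri-5 (839). None of the 57 major sperm protein genes had one, with an exact 95% upper bound of 6.27% (Fisher's exact test, adjusted p = 0.0264). In 19.05% of the circular shifts none of them had one either. Many of these genes are near-identical copies, which may limit mapping, but this was not measured here. Detoxification enzymes (3 of 185), neuropeptides (4 of 143) and nuclear hormone receptors (11 of 274) were below the other genes by Fisher's test, with adjusted p of 0.000803, 0.0264 and 0.0185. Their circular-shift adjusted p of 0.133, 0.125 and 0.242 did not pass the threshold. Members with peaks were gst-27 (873), ugt-50 (317) and gst-43 (239) among detoxification enzymes, flp-23 (641), ins-39 (435) and nlp-81 (376) among neuropeptides, and nhr-255 (1102), nhr-41 (747) and nhr-47 (692) among the receptors. The peak of gst-43 ranked 2788 in replicate 2, outside its top 2430 regions. The summit of gst-27 lay within 200 bp of a snoRNA gene. Those of flp-23, nhr-255, nhr-41 and the muscle gene lim-8 lay within 200 bp of a tRNA gene. With the nearest TSS only, the receptor, neuropeptide and sperm protein lists lost their calls (odds ratios 0.566, 0.431 and 0, Fisher's exact test, adjusted p = 0.15, 0.184 and 0.111). The same 3 lists lost them with the stronger peaks (odds ratios 0.516, 0.423 and 0, Fisher's exact test, adjusted p = 0.21, 0.345 and 0.257), and the sperm protein list with a window of 500 bp upstream (adjusted p = 0.0989). The odds ratio of detoxification enzymes was 0.182, and 0.117 with replicate 2's top regions alone.

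In all, 15 of the 29 lists passed Fisher's test, 10 above and 5 below the other genes. By the circular shifts 10 of 27 passed, all of them among the 15. The sperm protein list and the intestinal genes, with no member to compare, were left out of that test. No sperm protein gene had a peak in 19.05% of the shifts, and no intestinal gene in 17.19%. By each list's share of the genes with a peak, the unadjusted two-sided circular-shift p was 0.381 and 0.344. With no member observed, this p follows from those percentages alone and could not have been smaller. Shifted peaks also marked fewer genes, a mean of 792 against 1650, which makes a count of 0 easier to reach. The shifts therefore cannot decide on either list. Intestinal genes, 0 of 43, with an exact 95% upper bound of 8.22%, did not pass Fisher's exact test (adjusted p = 0.0807), but did with a window reaching 2000 bp upstream (adjusted p = 0.0222). Wnt pathway genes (6 of 30, adjusted p = 0.0607) and pan-neuronal genes (8 of 50, adjusted p = 0.104) did not pass Fisher's exact test. Their circular-shift adjusted p was 0.66 and 0.791. Wnt pathway genes did pass Fisher's test with either replicate's top regions alone (odds ratios 3.53 and 3.29), a window reaching 2000 bp upstream (4.12) and the stronger peaks (3.98), and pan-neuronal genes with the nearest TSS only (2.88) and with the same longer window (2.32). Early embryonic fate regulators had 5 of 46, among them mex-1 (725), the pharyngeal organ identity gene pha-4 (350) and skn-1 (245). Homeobox genes had 7 of 94, with ceh-39 (382), ceh-38 (375) and ceh-20 (314). Epidermis (5 of 54), pharynx (3 of 42), germ line (5 of 57), collagens (7 of 156), basic helix-loop-helix and T-box factors (4 of 59), vacuolar ATPase (3 of 21), Notch pathway (1 of 18), apoptosis (1 of 23) and the Sp and KLF family (1 of 6) did not pass either test, nor did the early fate and homeobox lists. Collagens did pass Fisher's exact test, below the other genes, without summits near tRNA genes (odds ratio 0.384, adjusted p = 0.0477). In the tissue lists, peaks lay at the neuronal genes syd-2 (536), unc-73 (376) and unc-2 (358) and at the pharyngeal genes peb-1 (381) and eat-20 (280). They also lay at the epidermal genes ajm-1 (339), hmp-1 (275) and dpy-17 (240) and at the germ line genes puf-9 (525), cgh-1 (336) and xnd-1 (330). The summit of ajm-1 lay within 200 bp of tRNA genes. The peaks of skn-1 and dpy-17 ranked 4200 and 3666 in replicate 2, outside its top 2430 regions. Both of these summits lay in coding exons. The shifts compare peaks with random positions and not with other active promoters.

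**Figure D2:**
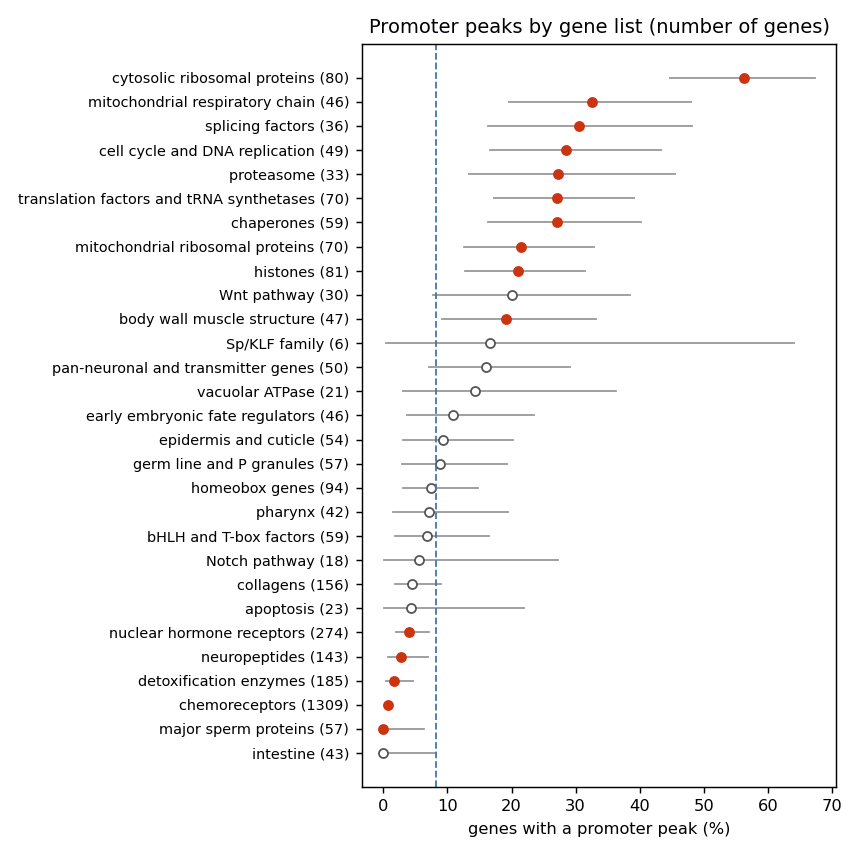
Percent of genes with a promoter peak (x axis) for each of 29 gene lists, with the number of genes in brackets and exact 95% intervals as bars. Filled red points passed Fisher's test after adjustment, the dashed line is the value of 8.26% over all genes, and cytosolic ribosomal proteins stand highest at 56.3%.

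The tagged gene and its family were looked at next. There were 5 thresholded summits within 20 kb of the middle of sptf-1 (I:10366621-10371697, plus strand). They lay at 10365880 upstream (signal value 565), 10366709 in a coding exon (278), and 10369254, 10369453 and 10370565 in introns (498, 257 and 485). Replicate 1 had no region at 10370565, where replicate 2 had a region of signal value 167. The family members sptf-2, sptf-3, klf-1, klf-2 and klf-3 had no thresholded promoter peak, and neither had unc-119, the gene mutated in the strain and the usual rescue marker of such transgenes. Regions of the pooled list below the threshold lay in the promoter windows of sptf-3 (182.1, rank 3839), unc-119 (131.4, rank 8945) and klf-1 (117.1, rank 11674).

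**Figure D3:**
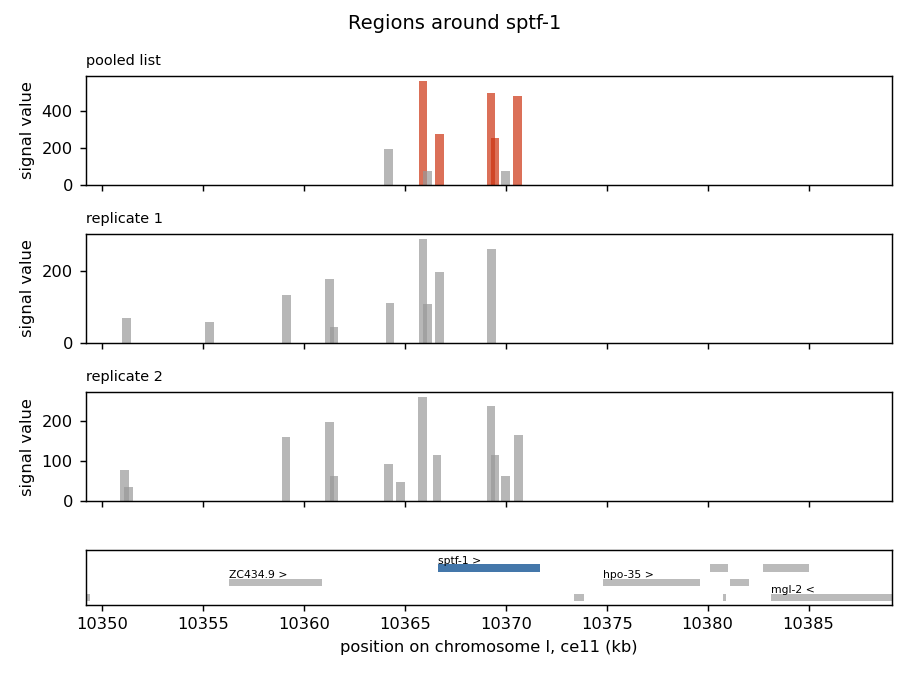
Regions of the pooled list and of each replicate within 20 kb of the middle of sptf-1, by position on chromosome I in kb (x axis) and signal value (y axis), with thresholded peaks in red and genes of at least 4 kb named. The 5 thresholded peaks lie at the promoter and inside sptf-1.

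Genes on X were compared with autosomal genes. Promoter peaks were found at 247 of 2731 X-linked genes (9.04%) and 1403 of 17242 autosomal genes (8.14%), an odds ratio of 1.12 that did not pass the threshold (95% interval 0.97 to 1.29, Fisher's exact test, p = 0.116). Replicate 1's top regions alone gave an odds ratio of 1.25 (Fisher's exact test, p = 0.00205), and assignment of each summit to its nearest TSS only gave 1.47 (p = 9.15e-07). Without summits near tRNA genes, a setting chosen after the values were seen, it was 1.07 (Fisher's exact test, p = 0.401). No circular-shift p was computed for this comparison, and neighbouring genes that share peaks can make Fisher's p too small. Shares ranged over the autosomes from 4.75% on V to 12% on I and III. Autosome centres (8.03% of 9597 genes) and arms (8.27% of 7645 genes) did not differ detectably (odds ratio 0.969, interval 0.867 to 1.08, Fisher's exact test, p = 0.594).

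Sites at tRNA genes were counted as well, a count planned as a gauge of non-specific signal. Of the nuclear summits, 233 (9.63%) lay within 200 bp of a tRNA gene, against a shift mean of 7.07, a 33-fold difference (two-sided permutation p = 0.0002, the smallest possible). A summit was found at 240 of 612 nuclear tRNA genes (39.2%, interval 35.3 to 43.2%). Replicate 1's top regions gave 231 such summits and those of replicate 2 gave 227. On X, which holds 276 of the tRNA genes, 519 peaks were found in all and 416 away from tRNA genes.

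**Figure D4:**
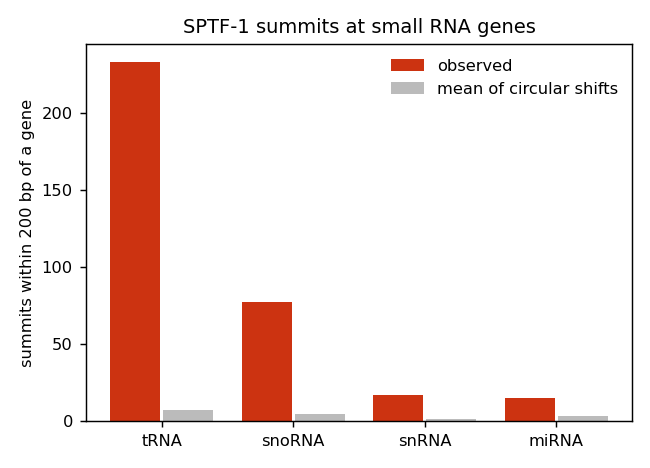
Number of nuclear summits within 200 bp of a tRNA, snoRNA, snRNA or miRNA gene (y axis) in red, beside the mean over circular shifts in grey. The 233 summits at tRNA genes compare with a mean of 7.07, and the 77 at snoRNA genes with 4.55.

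The last question was which sequences lay under the summits. Sp family factors are known to bind GC boxes and CACCC boxes. A GC box (GGGCGG) was present in 221 of 2419 windows of 100 bp at summits (9.14%) and in 87 of 4838 windows centred 300 bp to either side (1.80%), an odds ratio of 5.49 (95% interval 4.24 to 7.16, Fisher's exact test, adjusted p = 3.19e-44 over 12 motifs). A CACCC box (CCACCC) was present in 6.16% and 2.48%, an odds ratio of 2.58 (interval 2.00 to 3.33, Fisher's exact test, adjusted p = 6.61e-14). Against promoter windows matched on GC content, these odds ratios were 1.37 (interval 1.14 to 1.65, Fisher's exact test, adjusted p = 0.000964) and 1.55 (interval 1.24 to 1.95, adjusted p = 0.000213). Location was not matched, since 1086 of the 2419 summits lay outside promoter windows. Away from small RNA genes, the CACCC box was in 4.67% of promoter summit windows and 8.39% of those elsewhere. The GC-matched windows held it in 4.06%. For the GC box the shares were 10.5% at promoters, 7.93% elsewhere and 6.77% in GC-matched windows. The 5 other orders of 5 G and 1 C had odds ratios of 4.16 to 5.28 against flanks and of 1.28 to 2.11 against GC-matched windows, where 4 of the 5 were at or above the GC box. With replicate 1's top regions alone, all 5 orders (4.6 to 6.03) were above the GC box (4.35) against flanks, and with those of replicate 2 alone all 5 (3.88 to 4.74) were below it (5.17). The difference between words was not tested. The longer GC box GGGGCGGG was in 0.992% of summit windows and 0.103% of flanks (odds ratio 9.68, interval 3.62 to 32.5), and did not differ detectably from GC-matched windows (odds ratio 1.27, interval 0.725 to 2.17, Fisher's exact test, adjusted p = 0.417). Summit windows had a mean GC content of 49.6% and flanks 36.5%.

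GAGA repeats (GAGAGAGA) were present in 6.37% of summit windows and 1.10% of flanks (odds ratio 6.14, interval 4.44 to 8.59), and the odds ratio against GC-matched windows was 5.91 (interval 4.30 to 8.23, Fisher's exact test, adjusted p = 1.57e-32). GATA sites (WGATAR) were less frequent at summits (9.55% and 20.1%, odds ratio 0.421), as were splice acceptor sequences (TTTCAG, 5.00% and 20%, odds ratio 0.211). Against GC-matched windows these odds ratios were 0.794 and 0.415. The E-box CACGTG did not differ detectably from flanks (odds ratio 1.08, interval 0.738 to 1.58, Fisher's exact test, adjusted p = 0.708), and was less frequent than in GC-matched windows (odds ratio 0.627, Fisher's exact test, adjusted p = 0.00759).

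In the open search over all 6-mers, each counted with its reverse complement, 778 were more frequent and 606 less frequent at summits than in flanks after adjustment. Against GC-matched windows 394 were more frequent and 554 less frequent. The 10 with the highest odds ratios against flanks were CGCGCG (8.49), ACGCGC (8.18), GCGCGC (7.96), CCCGGG (7.51), GAGCGC (6.95), AGCGCG (6.74), GCACGC (6.62), CGCGCA (6.57), CGCACG (6.53) and CACGCG (6.41). Only 2 of these, ACGCGC and CGCGCA, were also among the top 10 against GC-matched windows. There CGCGCA led at 3.69, and GAGAGA (3.16) and ACACAC (3.32) were among the others.

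**Figure D5:**
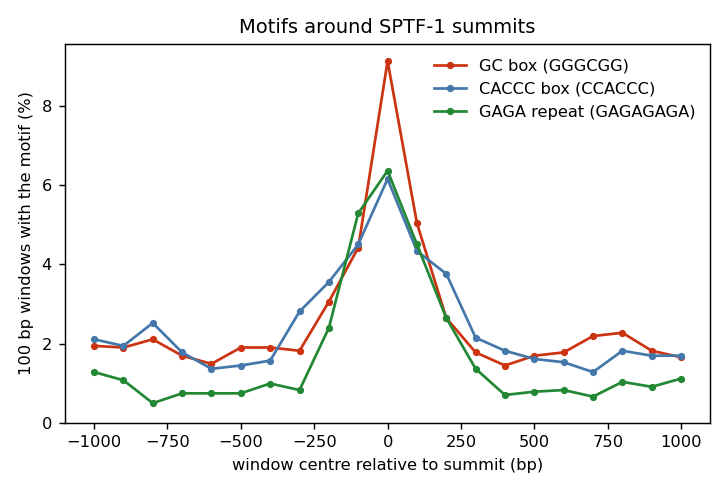
Percent of 100 bp windows holding a GC box, a CACCC box or a GAGA repeat (y axis) by distance of the window from the summit in bp (x axis), over 2419 nuclear peaks. All 3 are most frequent at the summit, at 9.14%, 6.16% and 6.37%.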

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

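No test was run on the mitochondrial peaks, and their ranks were looked at after the values were seen. The mitochondrial genome, which entered no comparison with genes or sequences, held 11 thresholded peaks, a signal outside the main measurement. Of the 20 strongest peaks of the whole list, 8 were mitochondrial, and the strongest had a signal value of 8188 against 3361 for the strongest nuclear peak. The top regions of replicate 1 held 12 mitochondrial regions and those of replicate 2 held 14. Peaks numbered 0.797 per kb there and 0.0241 per kb on the nuclear chromosomes. No explanation was tested.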

How the results depend on the processing

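Directions and calls for promoter share, tRNA genes, the GC box and the CACCC box were kept under every alternative run, each changing 1 choice, including the one chosen after seeing the data that left out summits within 200 bp of a tRNA gene and so gives no value for tRNA genes themselves. The top N of the pooled list moved nothing, since it is the same set of peaks. X against autosomes changed its call: the odds ratio was 1.17 with a window reaching 2000 bp upstream and 1.47 with the nearest TSS only, both past the threshold, and from 1.08 to 1.25 with a single replicate. The cause was not tested. With nearest-TSS assignment, which calls fewer genes by its construction, 9 gene lists passed in place of 15: 8 kept their call, 7 lost it and the pan-neuronal list gained one. By the circular shifts without the 2 lists of no member, also chosen after seeing the data, 10 passed. The stricter set, the upper part of the list by signal, had 1215 peaks and 959 genes by construction. Against GC-matched windows 394 6-mers were more frequent at summits in place of 778, and 297 of them were among the 778. The share of thresholded peaks in both replicates was 62% with 50% overlap of each region, 94.9% with double N and 99.3% with all regions. The signal correlation was 0.719 on ranks and 0.844 with the nearest summit within 100 bp. Leaving out the identical top N, the 15 called lists kept their call in 85 of 105 alternative values and lost it in 20, with no change of direction, and the other lists gained one in 8 of 98. These 20 losses were 7 with the nearest TSS, 5 with the stricter set, 3 with replicate 1 alone, among them nuclear hormone receptors (adjusted p = 0.0502 by Fisher's exact test), 2 with the window of 500 bp, and 1 each with the window of 2000 bp, with replicate 2 alone and without summits near tRNA genes, the last 3 all of body wall muscle. No paired analysis of samples was possible because there is 1 group only. Summit windows and their flanks came from the same places, and Fisher's test did not use this pairing. Read depth is unknown, so its limit on weak peaks could not be set.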

Other observations

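The tests of small RNA classes other than tRNA, of stronger against weaker peaks at them, of G-rich words of any order, of a GC box as the cause at most tRNA summits and of binding limited to the sptf-1 promoter were chosen after the data were seen. Small nucleolar RNA genes, whose products guide modification of ribosomal RNA, lay at 11 of the 25 strongest nuclear peaks. The peak of highest signal value, 3361, was beside the snoRNA gene W03C9.9 (II:11960628-11961086, ranks 5 and 7 in replicates 1 and 2). Other strong peaks lay at C51F7.3 and C51F7.4 in an intron of frm-7 (3264), at B0334.12 (3115), ZK265.10 (2863), T03F7.8 (2809), T06C12.16 (2695) and ZK994.7 (2435). Summits lay within 200 bp of 76 of 346 snoRNA genes, and the 77 summits there were 16.9-fold above the shift mean of 4.55. The snRNA class had 17 summits, 12-fold above, with the SL2 trans-splicing leader genes sls-2.4 (1284), sls-2.2 (866) and sls-2.1 (789) among them. The miRNA class had 15 summits, 5.05-fold above, led by mir-51 (2216) and mir-52 (1534), members of the mir-51 family. All 3 classes had a permutation p of 0.0002, the smallest that the shifts can give (adjusted p = 0.000267 over 8 classes). Pseudogenes (20 summits, 0.231-fold) and piRNA genes (8 summits, 0.125-fold) were below the shift mean. The lincRNA class had 18 summits, 2.32-fold above (permutation, adjusted p = 0.00366), and rRNA genes had 0.

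Summits at tRNA, snoRNA and snRNA genes were more frequent among the stronger peaks. Of the 25 strongest nuclear peaks 16 lay within 200 bp of a tRNA, snoRNA, snRNA or miRNA gene, of the 100 strongest 60, and of all 2419 peaks 341 (14.1%). Summits at tRNA genes numbered 185 in the upper part of the list by signal (1204 nuclear peaks) and 48 in the lower part (odds ratio 4.41, 95% interval 3.16 to 6.26, Fisher's exact test, adjusted p = 1.94e-21), and those at snoRNA genes 61 and 16 (odds ratio 4.0, interval 2.26 to 7.47, adjusted p = 3.49e-07). Those at snRNA genes numbered 14 and 3 (odds ratio 4.75, interval 1.32 to 25.8, Fisher's exact test, adjusted p = 0.0189), and for those at miRNA genes, 9 and 6, no difference was detectable (odds ratio 1.52, interval 0.481 to 5.2, Fisher's exact test, adjusted p = 0.674). With all summits near small RNA genes left out, cytosolic ribosomal protein genes had promoter peaks at 44 of 80 (odds ratio 15.1, Fisher's exact test, adjusted p = 3.38e-27).

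The 9-mer CTGCGTCTC was found in 139 of 2419 summit windows (5.75%) and 31 of 4838 flank windows (0.641%), and at tRNA genes in 0 of 233. It was picked from these same windows after their values were seen, so an excess follows in part from the choice and no test is given.

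The summits at tRNA genes were weighed against reads shared between identical gene copies. Among tRNA genes of unique sequence 35 of 143 had a summit (24.5%, interval 17.7 to 32.4%), 20.9 times the shift mean of 1.17%. This argues against reads shared between identical copies as the whole cause. Genes of repeated sequence did have one more often (43.7%, odds ratio 2.39, interval 1.55 to 3.77), so a part from shared reads stays open. Near-identical copies, and unique genes close to repeated ones, were not set apart. A GC box was more frequent in the tRNA summit windows than in their flanks (odds ratio 4.50, interval 1.70 to 13.2), but only 6.44% of these windows held one, so it cannot be the cause at most of them. General signal at very active loci stays open, since no library without the tagged factor was analysed here. This holds also for the other small RNA genes and for the lists of broadly expressed genes. No biological explanation was tested.

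Away from tRNA genes the GC box kept an odds ratio of 5.58 (interval 4.27 to 7.36) at summits, which argues against tRNA genes as its source. Against GC-matched windows its odds ratio was 1.37, above 1 as the bound written beforehand against base composition required. That bound was too narrow, since matching on GC content leaves G-rich words of any order in excess. The other orders had a highest odds ratio of 2.11, with 4 of 5 at or above the GC box. Of these orders, GGGGCG (1.28) and GGCGGG (1.38) lie inside the longer GC box GGGGCGGG, so its sites can raise them too. The others, CGGGGG (2.02), GCGGGG (1.83) and GGGGGC (2.11), do not lie inside it. Each can still overlap a GC box that has further G beside it, so such sites can raise these orders as well. Against flanks the replicates differed, with all 5 orders above the GC box in replicate 1's top regions and all 5 below it in those of replicate 2. Recognition of the GC box and a G-rich base composition therefore cannot be told apart here.

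The peaks at sptf-1 were weighed against extra copies of the transgene's genomic fragment, which would raise signal across the whole fragment. The pooled list held 8 regions within 20 kb of the middle of the gene, at percentile 45.4 of the same count over all genes. This was below the 95th percentile of 25 regions, the bound written beforehand against this explanation. The replicate lists held 10 and 13, at percentiles 53.8 and 66.1, so regions were not unusually many there. A count of regions does not measure their signal, and a control of the same strain would carry the same copies. The counts therefore cannot decide on extra copies. The pooled list lacks 2 regions here that both replicates share, so the replicate lists are the safer measure. Of the 5 thresholded summits there (percentile 99.5), 3 lay outside promoter windows, so the sites were not limited to the promoter. Binding of SPTF-1 at its own gene stays a hypothesis, and the strain of the control was not given in the sources used here.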
